A study of Oryza sativa Japonica Group with 20 samples.

How the data were processed

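CUT&Tag libraries of rice root tips were made with antibodies against H3K27me3, H3K4me3, EMF2b and PLT5 and with IgG, in WT and plt345 plants, 2 replicates per group. Per the labels' protocols, seedlings grew on half-strength medium under 14 h of light and 10 h of dark at 28 and 24 °C. Per the submitters' processing notes, Trim Galore 0.6.6, Bowtie2 2.4.4, deepTools 3.5.0 and MACS2 2.2.7.1 were used; their roles, the control library, the handling of duplicate reads and the genome build are not given in the sources used here. Each of the 14 libraries used here has a peak list of its own from the authors, so peaks were called in each sample separately and not on pooled samples. H3K27me3 lists are in the broad peak format and the rest in the narrow peak format. The lists have no header, so columns were read in the order MACS2 writes them. Each deposited list gives a fold enrichment, which is a ratio to the background modelled for that library, and a −log10 p and −log10 q, as the authors' peak caller gave them. The deposited score is 10 times the −log10 q in broad lists and 10 times the −log10 p in narrow lists, and the values showed this for at least 99.6% of peaks of every library. The peak start and end are other deposited columns, in bp. Peak names record a p cutoff of 1e-05 for narrow lists and a broad cutoff of 0.1, and the smallest values in the lists fit these. Scores, folds and q-values of separately called lists depend on depth and background, so they were used to describe, rank or filter peaks within a list and were not tested between lists.

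For each antibody the peaks of its 4 libraries were merged into regions, and a region was present in a library when that library's peaks covered at least 150 bp of it. A lost region was present in both WT libraries and neither plt345 library, and a gained region the reverse. The 2 ways of putting 1 WT and 1 plt345 library on each side served as the reference, since 2 against 2 libraries cannot pass 0.05 in an exact permutation test (smallest two-sided p = 0.333). These mixed splits regroup the same 4 libraries, so they show disagreement of replicates only. A technical difference shared by both libraries of a genotype would raise lost or gained counts but not mixed ones. Regions that another mark covered were called from both WT libraries for presence and from neither for absence. PLT5 sites are merged peaks found in both PLT5 libraries, and a region was bound when it overlapped a site by at least 1 bp. All other regions counted as unbound, also those with a PLT5 peak in only 1 library. Bivalent regions are H3K27me3 regions with at least 150 bp of H3K4me3 in both libraries of a genotype. Associations were tested across regions by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment within a family, with 95% intervals on the log odds scale (Woolf); regions are not independent replicates, so these p-values compare these libraries and not the genotypes at large. The same odds ratio was computed for regions present in a first and absent from a second library, for pairs of a genotype and pairs across genotypes. Overlap of sites with marks was set against 1000 circular shifts of the sites along each chromosome with a fixed seed. Such shifts do not control for accessible chromatin. Shares have Wilson 95% intervals, or exact Clopper-Pearson ones where stated. Intervals cover counting error only. Nothing states that replicates came from separate plants or cultures, so the spread between them, and p-values that rest on it, may be technical. Read depth per sample is unknown. The number of peaks per library, and the −log10 q reached at a similar fold, are the only guides to precision.

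Tests, comparisons, the alternative settings and the rule for named regions were written before the data were examined, for genes. No genome or annotation on the assembly of the lists was used here. The gene table at hand is of assembly ASM3414082v1, which could not be matched to the unstated assembly of the lists. Every planned gene result was therefore computed for regions, which departs from the written design. The planned test of H3K4me3 gain at H3K27me3 genes asks for regions with H3K4me3 in no library, which merged H3K4me3 regions do not hold, so gained regions were compared with lost ones; gains at PLT5-bound regions were treated in the same way. Gene lists, cell type markers, the position of PLT5 peaks relative to genes and the loci of PLT3, PLT4 and PLT5 were not analysed here. The rule for named items became: for each antibody and direction the 6 regions with the largest mean covered length in the genotype that has them, the 10 PLT5 sites with the highest mean −log10 q, and the 6 PLT5-bound regions with the longest bivalent stretch, without unplaced sequences. The text gives the first 3 of each list by rank, and others of a list only to complete a count over it; for lost H3K4me3 regions it gives all 6. The shares of lost, kept and gained regions with another mark and a family of 7 odds ratios of loss or gain by such marks, 3 of them printed, were added after the data were examined, as were the comparisons of EMF2b sites without PLT5, of the 100 strongest PLT5 sites and of runs of lost regions.

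Alternatives were a covered length of 1 or 500 bp, peaks above the 25th percentile of −log10 q, equal numbers of peaks or equal covered length per library by −log10 p, chromosomes 1 to 12 only, marks overlapping in bases, PLT5 peaks of either library or of each alone or above the median q, overlap of at least 50% of a site, strata of WT covered length or peak strength, replicate pairs as strata, and leaving out each library. With replicate pairs as strata, a change is judged between the WT and plt345 libraries of the same replicate number. A loss is then absence from 1 plt345 library, and a region can enter with each pair. The IgG samples and the plt345 PLT5 samples were not used here. Positions are given 1-based. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, figures matplotlib 3.10.9, and interval code was checked against bedtools 2.31.1 on 12590 PLT5 peaks. Region calling was tested on simulated data made from the WT H3K27me3 lists. With 200 regions deleted from copies of them, all 200 were called lost and no region was called gained among 25890. With 5% of peaks also dropped at random from every list, 87.5% of the 200 were recovered, with 45 other regions called lost and 61 called gained among 25873. Both simulated genotypes were copies of the same 2 WT lists, so error rates in the real lists can be higher. Mixed splits of the real H3K27me3 lists gave 196 to 224 regions. A simulated odds ratio of 3.86 was estimated as 3.81 (95% interval 3.50 to 4.15) over 25875 regions. Of 2000 simulated sites placed at random 11.9% lay on WT H3K27me3 peaks against 11.2% in shifts (permutation p = 0.164).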

Results

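CUT&Tag, which cuts and tags chromatin where an antibody has bound, was applied to nuclei of rice root tips of about 0.8 cm taken from 7-day seedlings. Wild-type (WT) plants of cultivar ZH11 were set beside plt345, a mutant of PLT3, PLT4 and PLT5, members of the PLETHORA family of AP2-type transcription factors that act in root meristems. Peak lists were used for 14 of the 20 samples: 2 libraries per genotype for H3K27me3 (the mark laid down by Polycomb repressive complex PRC2), for H3K4me3 (a mark of the start of active genes) and for EMF2b (a PRC2 subunit), and 2 WT libraries for PLT5. The 6 IgG and plt345 PLT5 samples were not analysed here, so binding of PLT5 has no mutant control. The WT H3K27me3 libraries held 23957 and 24185 peaks and the plt345 libraries 20841 and 20942. H3K4me3 gave 25762 and 25165 peaks in WT and 27182 and 26841 in plt345, and EMF2b gave 15486 and 14851 in WT and 15342 and 17891 in plt345. The PLT5 lists held 12590 and 10822 peaks. Read depth is unknown because the lists carry no counts, and the assembly is not given in the sources used here, so peaks are named by the positions in the lists and were not assigned to genes. The peaks, fold enrichments and q-values are the authors', called in each library separately.

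The first question was whether the amount of each mark differed between the genotypes. H3K27me3 covered 31.6 ± 0.641 Mb in WT and 27.6 ± 0.0795 Mb in plt345 (SD, n = 2 each), a ratio of 0.876 of plt345 to WT, and the peak number was 24071 ± 161 in WT and 20892 ± 71.4 in plt345 (SD, n = 2 each). H3K4me3 peaks were more numerous in plt345, at 27012 ± 241 against 25464 ± 422 in WT, but narrower, at a mean of 895 ± 12.4 bp against 958 ± 6.23 bp, and the covered length was 24.2 ± 0.119 Mb against 24.4 ± 0.246 Mb, a difference within the spread of the libraries. EMF2b peaks had a mean width of 504 ± 19.2 bp in plt345 and 639 ± 18.8 bp in WT, and covered 8.39 ± 1.23 Mb against 9.69 ± 0.572 Mb. The shortest EMF2b peak was also shorter in plt345, at 247 and 249 bp against 290 and 285 bp in WT. For H3K4me3 it was 272 and 277 bp against 290 and 295 bp. The fragment length used in peak calling is not given in the sources used here. A difference in it between the genotypes would change EMF2b and H3K4me3 widths and covered lengths without a change in occupancy. For H3K27me3 peak number and length, H3K4me3 peak number and width, and EMF2b length and width, both plt345 values lay on the same side of both WT values. The exact two-sided permutation test gave p = 0.333 for each of these, the smallest p that 2 against 2 libraries allow, so none can pass 0.05. When every library was held to an equal number of peaks the H3K27me3 length ratio was 0.938 and the H3K4me3 ratio 0.963.

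H3K27me3 regions disappeared more often than they appeared in plt345. Of 20610 regions with peaks in both WT libraries, 2412 (11.7%) had no peak in either plt345 library, and 762 of the 17403 regions of both plt345 libraries had none in WT. The share lost lay between 10.5% and 13.1% on each of the 12 chromosomes. The 3 longest lost regions were chromosome 7 from 6879908 to 6883626, where peaks covered 3380 ± 479 bp in WT (SD, n = 2), chromosome 11 from 3948720 to 3953021 with 3225 ± 1244 bp, where the WT libraries differed widely, and chromosome 4 from 2778143 to 2781347 with 2925 ± 273 bp. None of the 6 longest lost regions carried H3K4me3 or PLT5 peaks in WT. The 3 longest gained regions were chromosome 7 from 15872133 to 15875613, with 3261 ± 155 bp covered in plt345, chromosome 3 from 21459013 to 21462620, with 2993 ± 583 bp, and chromosome 1 from 20257472 to 20260536, with 2958 ± 151 bp. H3K4me3 was present in all 4 libraries at 3 of the 6 longest gained regions, those of chromosomes 7 and 3 and chromosome 11 from 26921244 to 26924342. Lost regions were short, with a median WT width of 520 bp against 1538 bp for kept ones, and 66.8% of the 3.62 Mb of H3K27me3 bases lost from WT lay in regions that were not themselves lost. Regions that kept the mark narrowed from a mean of 1705 bp covered in WT to 1575 bp in plt345. When 1 WT and 1 plt345 library were put on each side, the 4 counts lay between 196 and 224. The excess of losses depended on the amount called: equal numbers of peaks per library gave 1455 lost and 1319 gained, and equal covered length gave 988 lost and 2036 gained. The plt345 lists also reached a lower median −log10 q, 2.73 and 2.59 against 3.34 and 3.36 in WT, at a similar median fold. Calls that ask for fewer libraries give more regions: without WT replicate 1 there were 3960 lost and 1159 gained, without WT replicate 2 3919 lost, without plt345 replicate 1 1574 gained and without plt345 replicate 2 1496 gained, and the lost length was 5.64 to 6.28 Mb.

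**Figure D1:**
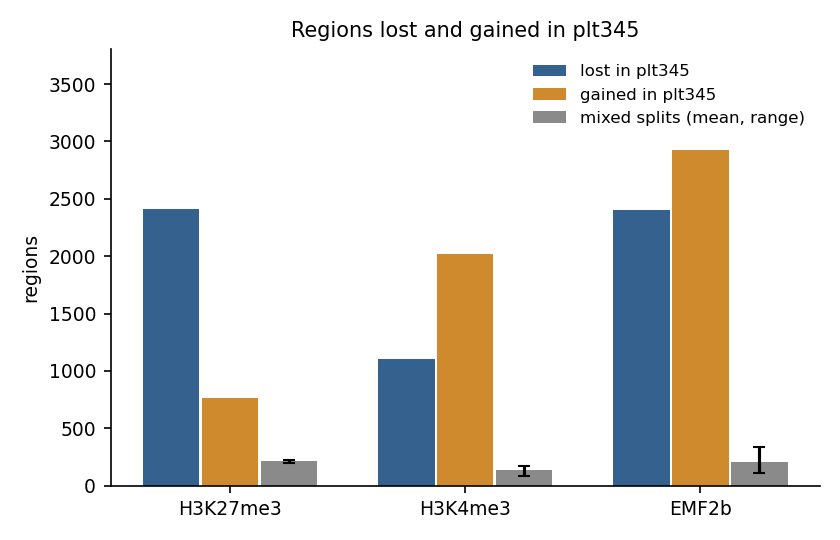
Number of regions (y axis) present in both libraries of a genotype and absent from both of the other, for each antibody; grey bars give the mean of the counts from the 2 mixed splits, with lines from the lowest to the highest. Every lost or gained count, the smallest being 762, lies above the highest mixed count of 337. Mixed counts show disagreement of replicates only. They cannot separate a genotype effect from a technical difference shared by the libraries of a genotype.

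By number, H3K4me3 changed in the other direction, with 2020 regions gained and 1108 lost, but by length 1.80 Mb were gained and 1.82 Mb lost. The gained regions were 8.28% of the 24407 found in both plt345 libraries and the lost ones 4.75% of the 23331 found in both WT libraries, while mixed splits of the same libraries gave 87 to 173. The 3 longest gained regions lay on chromosome 11 from 14185614 to 14188131 (2266 ± 343 bp covered in plt345; SD, n = 2), chromosome 10 from 11567693 to 11569779 (2072 ± 21.9 bp) and chromosome 10 from 3727871 to 3729960 (2066 ± 30.4 bp), and none of the 6 longest had PLT5. The longest lost region, on chromosome 10 from 657553 to 659814, had 2228 ± 29.7 bp of H3K4me3 in WT and none in plt345. This region and those of chromosome 7 from 4165362 to 4167550 and chromosome 5 from 3354435 to 3356311, 3 of the 6 longest, were bound by PLT5 and kept both H3K27me3 and EMF2b peaks in all 4 libraries. The other 3 had neither PLT5 nor EMF2b: the region of chromosome 12 from 18785394 to 18787599 had H3K27me3 in all 4 libraries, that of chromosome 2 from 22438806 to 22440989 in 1 WT and both plt345 libraries and that of chromosome 3 from 647857 to 649663 in 1 WT library only. H3K27me3 peaks of both WT libraries lay on 37.7% of lost regions (95% Wilson interval 34.9 to 40.6%), 17.0% of kept regions and 20.7% of gained regions, EMF2b on 39.7%, 24.5% and 4.31%, and PLT5 on 33.8%, 23.8% and 4.90%. EMF2b peaks of both plt345 libraries lay on 39.4% of lost, 28.7% of kept and 9.26% of gained regions. Equal numbers of peaks per library gave 1436 lost and 1478 gained, so that the excess of gains was not seen at that setting, while equal covered length gave 943 lost and 2120 gained. Without WT replicate 2 there were 1835 lost, and with any 1 library left out 2.70 to 2.99 Mb were lost and 2.45 to 2.96 Mb gained.

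**Figure D2:**
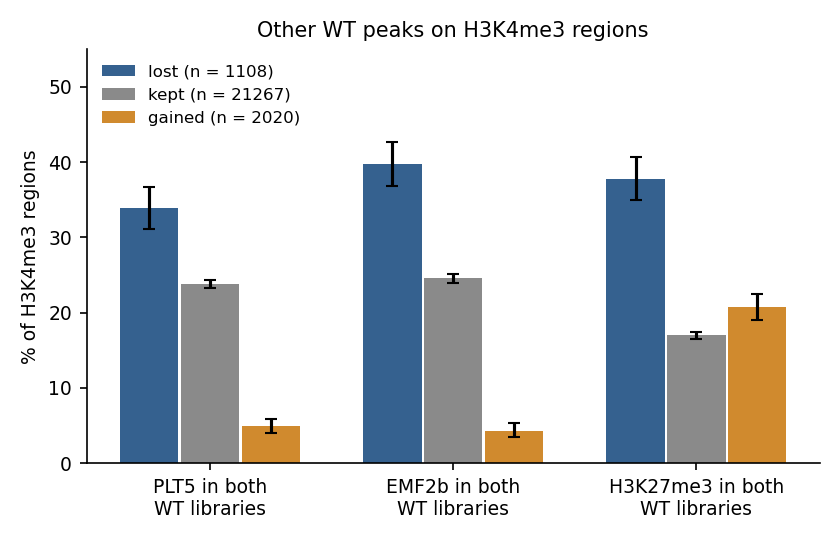
Share of H3K4me3 regions (y axis, percent) that carry PLT5, EMF2b or H3K27me3 peaks of both WT libraries, for regions lost, kept or gained in plt345; lines are 95% Wilson intervals, which cover counting error only. PLT5 is on 33.8% of lost and 4.90% of gained regions.

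A larger share of EMF2b regions changed than of regions of either histone mark, and EMF2b replicates also shared fewer peaks, at 74.7 to 87.8% against 87.5 to 90% for H3K27me3 and 92.9 to 94.8% for H3K4me3. Of 12607 regions in both WT libraries 2399 (19.0%) were lost, and 2926 (22.3%) of the 13120 regions in both plt345 libraries were gained, against 111 to 337 in the mixed splits. By length the order was the reverse, with 2.36 Mb lost and 1.40 Mb gained. The longest lost regions were on chromosome 6 from 28862942 to 28864814 (1786 ± 107 bp in WT; SD, n = 2), chromosome 2 from 9639836 to 9641601 (1656 ± 146 bp) and chromosome 2 from 18940859 to 18942526 (1648 ± 28.3 bp), and 2 of the 6 longest were PLT5-bound. The longest gained regions lay on chromosome 2 from 6509408 to 6511128 (1419 ± 286 bp in plt345), chromosome 7 from 23782942 to 23784431 (1348 ± 201 bp) and chromosome 11 from 18244496 to 18246020 (1325 ± 283 bp). H3K4me3 of WT was found on 60.4% of kept EMF2b regions, 38.3% of gained and 17.8% of lost ones, and PLT5 on 66.9%, 12% and 17.4%. EMF2b regions with WT H3K4me3 were lost less often than those without it, at 6.88% against 33.1% (odds ratio 0.150, 95% interval 0.134 to 0.167), a contrast not set against disagreement of replicates. The balance of lost and gained EMF2b regions turned with the setting, to 2777 lost and 2416 gained at equal numbers of peaks, and to 2333 lost and 813 gained when 500 bp had to be covered. At equal covered length 1368 were lost and 3438 gained. Without WT replicate 2 there were 3823 lost and 3639 gained regions, so that the balance turned, and without plt345 replicate 1 2809 lost and 5518 gained. The lengths were 3.97 Mb lost without WT replicate 2, 3.01 Mb gained and 2.71 Mb lost without plt345 replicate 1, where the order turned, and 2.11 Mb gained without plt345 replicate 2.

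Bivalent domains, where H3K27me3 and H3K4me3 lie at the same place, are the subject named by the study's title. In WT 4461 of 20610 H3K27me3 regions (21.6%) also carried H3K4me3, and in plt345 3596 of 17403 (20.7%) did. The bases under both marks came to 2.17 Mb in WT and 1.58 Mb in plt345. H3K4me3 regions overlapped H3K27me3 at 19.7% in WT and 15.2% in plt345, against 13.8% and 11.6% in 1000 circular shifts along the chromosomes (one-sided permutation p = 0.001 for both, the smallest the shifts can give). Of the 4461 bivalent WT regions, 2751 (61.7%) had both marks in both plt345 libraries, 478 had lost H3K27me3 and 488 (10.9%) had lost H3K4me3, with 71 in both sets. A further 433 (2.82%) of the 15380 WT regions with H3K27me3 alone had gained H3K4me3. The counts of bivalent regions were smaller when 500 bp had to be covered, at 2071 in WT and 1672 in plt345, and with peaks above the 25th percentile of q only, at 2210 and 1770. At equal covered length per library the order turned round, with 3204 bivalent regions in WT and 3512 in plt345. Peaks of both marks at a region do not show that they share a nucleosome or a cell.

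A comparison of bivalent with H3K27me3-only regions asked where each mark was lost. H3K27me3 was lost at 10.7% of bivalent and 12% of H3K27me3-only regions (odds ratio 0.879, 95% interval 0.790 to 0.978, two-sided Fisher's exact test p = 0.0186, adjusted p = 0.0186 over 2 comparisons, across regions, which are not independent replicates). The difference depended on the setting. It was larger within strata of WT covered length (Mantel-Haenszel odds ratio 0.657) or peak strength (0.815, strata chosen after the data were examined), when 500 bp had to be covered (0.779, exact p = 0.00262) and when the marks had to overlap in bases (0.854, exact p = 0.00619). The odds ratio was 1.09 (exact p = 0.209) with peaks above the 25th percentile of q only, 0.909 (p = 0.178) at equal numbers of peaks, 0.904 at 1 bp (p = 0.0585) and at equal covered length (p = 0.236), and without plt345 replicate 1 it was 1.04, without plt345 replicate 2 0.995, without WT replicate 2 0.935 and without WT replicate 1 0.885 (exact p = 0.00471). With replicate pairs as a block, where a loss is absence from 1 plt345 library, the Mantel-Haenszel odds ratio was 1.03, in the other direction. Disagreement between replicates of a genotype gave odds ratios of 1.06 to 1.31 at H3K27me3 regions with H3K4me3, and single WT and plt345 libraries 0.991 to 1.06 for absence in plt345. H3K4me3 was lost from 9.64% of its WT regions with H3K27me3 and from 3.37% of those without it (odds ratio 3.05, 95% interval 2.68 to 3.48, Fisher's exact test p = 2.31e-58, adjusted p = 4.04e-58 over 7 comparisons). Among H3K4me3 regions that changed, 50% of the 836 with H3K27me3 were gains and 71.8% of the 2105 without it (odds ratio 0.393, 95% interval 0.333 to 0.464, Fisher's exact test p = 2.02e-28, adjusted p = 4.03e-28). Disagreement between replicates of a genotype was also more frequent at H3K4me3 regions with H3K27me3, at odds ratios of 1.29 to 1.65, while single WT and plt345 libraries gave 2.28 to 2.46 for absence in plt345.

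PLT5 sites were then compared with the other WT maps. A PLT5 peak was found in both libraries at 8781 sites. Of these, 76.6% overlapped EMF2b in both WT libraries, 65.9% H3K4me3 and 45.9% H3K27me3, and 28.7% overlapped bases under both histone marks. Shifted sites gave 4.69%, 10.8%, 11.5% and 1.48% (1000 circular shifts, one-sided permutation p = 0.001 for each, the smallest the shifts can give). The shifts place sites anywhere on a chromosome, so accessible chromatin shared by all antibodies is not excluded as the source of overlap. By histone state 2590 sites (29.5%) had both marks, 3197 (36.4%) H3K4me3 only, 1442 (16.4%) H3K27me3 only and 1552 (17.7%) neither, and EMF2b was present at 83.3% of the sites with both and 72.7 to 75.2% of the others. The strongest sites were on chromosome 12 from 13349157 to 13349936, with a PLT5 −log10 q of 198 ± 11.3 (SD, n = 2), chromosome 8 from 12797706 to 12798237, with 191 ± 4.64, and chromosome 10 from 14535072 to 14535781, with 191 ± 7.09. Of the 10 strongest, all carried H3K27me3 and EMF2b in both libraries of both genotypes, and all but the site on chromosome 12 from 21599948 to 21600459, which lacked it in plt345 replicate 2, also carried H3K4me3. Among the 100 strongest, H3K27me3 was present at 89% in WT and 61% in plt345, and all 3 other antibodies together at 62% and 47%. The longest bivalent stretches among PLT5-bound regions lay on chromosome 1 from 33516414 to 33522378, with 4311 bp under both marks in WT and 2711 bp in plt345, chromosome 9 from 4705549 to 4711292, with 4116 and 3383 bp, and chromosome 1 from 33534802 to 33539492, with 4098 and 3549 bp. The stretches were ranked by their WT length, so that shorter ones in plt345 follow in part from the ranking. All 6 longest regions kept EMF2b and H3K4me3 in both plt345 libraries.

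**Figure D3:**
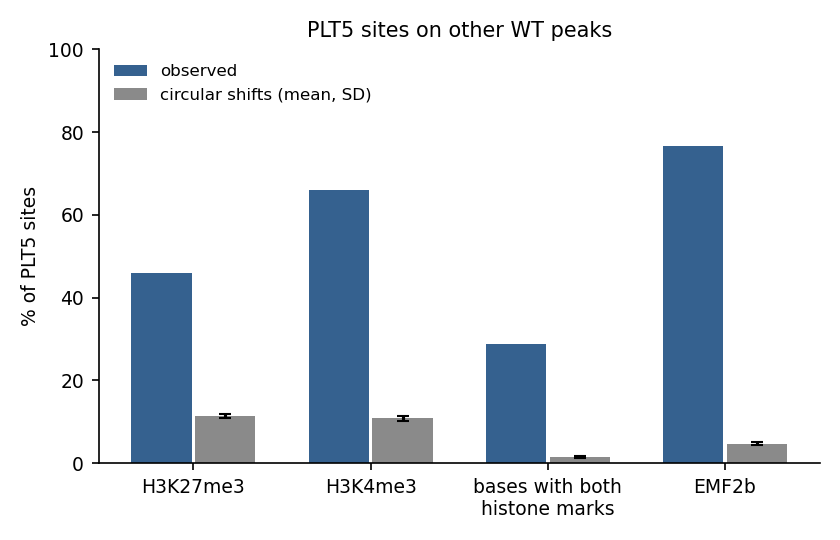
Share of the 8781 PLT5 sites (y axis, percent) that overlap peaks of both WT libraries by at least 1 bp, beside the mean and SD over 1000 circular shifts. EMF2b is at 76.6% of sites against 4.69% of shifted ones. The shifts do not control for accessible chromatin.

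The last question was whether changes in plt345 coincided with PLT5 binding in WT. At PLT5 sites H3K27me3 was present at 51.6 ± 0.548% in WT libraries and 41.9 ± 0.193% in plt345 libraries, and H3K4me3 at 69.3 ± 0.491% and 62.9 ± 0.266% (SD, n = 2 each). EMF2b was present at 81.1 ± 0.153% and 80.1 ± 3.54%, a difference within the spread of the libraries. H3K4me3 regions bound by PLT5 were lost more often than unbound ones, at 6.53% against 4.17% (odds ratio 1.61, 95% interval 1.41 to 1.83, Fisher's exact test p = 1.59e-12, adjusted p = 2.38e-12 by Benjamini-Hochberg over 6 comparisons). Few PLT5-bound H3K4me3 regions were gained: 99 of the 474 that changed (20.9%), against 72.4% of unbound ones (odds ratio 0.101, 95% interval 0.0795 to 0.128, adjusted p = 1.32e-99, Fisher's exact test). H3K27me3 was lost from 11.2% of bound and 11.8% of unbound regions (odds ratio 0.945, 95% interval 0.848 to 1.05, Fisher's exact test p = 0.325), and gains made up 10.5% of its 504 bound changes against 26.6% of unbound ones (odds ratio 0.325, 95% interval 0.241 to 0.438). EMF2b was lost from 6.21% of bound and 33.6% of unbound regions (odds ratio 0.131, 95% interval 0.117 to 0.146), but replicates of a genotype also differed less at bound EMF2b regions, with odds ratios of 0.151 to 0.213. For H3K4me3 replicates of a genotype gave 0.668 to 0.764, and single WT and plt345 libraries 1.35 to 1.48. With PLT5 peaks limited to those above the median q, regions of weaker PLT5 peaks counted as unbound. The H3K4me3 excess was absent in that comparison (odds ratio 0.958, p = 0.657, Fisher's exact test). It was not adjusted for H3K27me3 or EMF2b. Both lay more often on PLT5-bound than on unbound WT H3K4me3 regions (odds ratios 6.88 and 32.8). For H3K27me3 loss the direction depended on the setting: the Mantel-Haenszel odds ratio was 0.710 within strata of WT covered length and 1.06 with replicate pairs as a block, and the odds ratio was 1.01 at equal covered length, 1.07 without plt345 replicate 1 and 1.05 without plt345 replicate 2. For EMF2b, gains were 45.7% of bound changes and 56.5% of unbound ones (odds ratio 0.648, 95% interval 0.556 to 0.755), which was 0.982 without WT replicate 1 and turned to 1.16 without WT replicate 2. PLT5 sites were mapped in WT alone, and the chance of a PLT5 call at regions gained in plt345 was not measured.

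**Figure D4:**
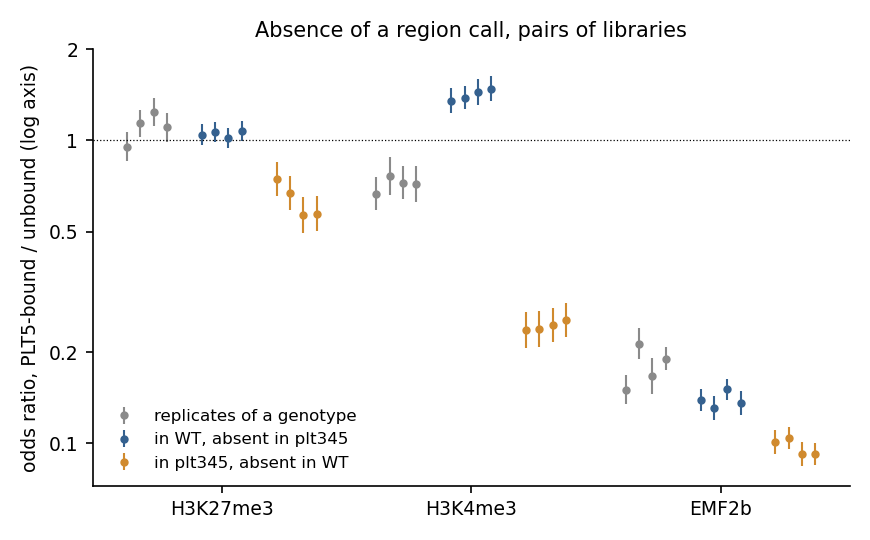
Odds ratio (y axis, log scale) that a region call of the first library is absent from the second, PLT5-bound against unbound, for each ordered pair of libraries, with 95% intervals; points are grouped by antibody and by whether the pair is of a genotype or between genotypes. For H3K4me3 the pairs of a genotype lie between 0.668 and 0.764 and those from WT to plt345 between 1.35 and 1.48.

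Loss of EMF2b and loss of H3K27me3 did not detectably coincide. Where both were present in both WT libraries, H3K27me3 was lost from 89 of 669 regions that had lost EMF2b (13.3%) and from 502 of 4350 that had not (11.5%). The odds ratio was 1.18 (95% interval 0.924 to 1.5, two-sided Fisher's exact test p = 0.197), so an excess of up to 1.5 is not excluded by counting error. EMF2b sites overlapped H3K27me3 at 40.4% in WT and 30.5% in plt345, against 11.8% and 9.18% in shifts (one-sided permutation p = 0.001 for both, the smallest the shifts can give). Their overlap with H3K4me3 was 50.8% in WT and 49.7% in plt345, against 11.1% and 10.2% in shifts (permutation p = 0.001 for both, again the smallest). The odds ratio was 0.912 with peaks above the 25th percentile of q only and 0.964 without plt345 replicate 2 of H3K27me3.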

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

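Strata of peak strength, the set without the 500 strongest PLT5 sites and every setting of H3K4me3 loss by EMF2b or H3K27me3 were chosen after the data were seen; the other settings were planned. Outside the settings that leave out a library, 143 of the recomputed values kept their direction and side of the threshold, or for counts stayed within 1.5 times, 12 moved, 6 reversed, 3 lost the call and 1 gained it. At equal numbers of peaks H3K27me3 had 1455 regions lost and 1319 gained, the plt345 to WT length ratio was 0.938 for H3K27me3 and 0.963 for H3K4me3, and the odds ratio of H3K27me3 loss at bivalent regions was 0.909. At equal covered length 988 H3K27me3 regions were lost and 2036 gained, 1368 EMF2b regions were lost, and the odds ratios of H3K27me3 loss were 0.904 at bivalent and 1.01 at PLT5-bound regions. A requirement of 500 bp left 813 EMF2b gains and 2071 and 1672 bivalent regions in WT and plt345, while 1 bp gave 0.904 for H3K27me3 loss at bivalent regions and by construction left the lost and gained counts as they were, since a peak is longer than 150 bp. Peaks above the 25th percentile of q gave 2210 and 1770 bivalent regions, an odds ratio of 1.09 for H3K27me3 loss at bivalent regions and 0.912 for EMF2b loss with H3K27me3 loss. PLT5 peaks above the median q, with weaker ones counted as unbound, gave 0.958 for H3K4me3 loss at bound regions. Strata of WT covered length gave 0.710 for H3K27me3 loss at bound regions. A longer overlap or a stricter threshold lowers counts by construction; for the other changes the cause was not tested.

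Replicate pairs taken as a block gave odds ratios of 1.03 for H3K27me3 loss at bivalent regions and 1.06 (p = 0.0338) for H3K27me3 loss at PLT5-bound regions, and changed no other call; replicate numbers did not pair the libraries, since the correlation of replicate differences between genotypes was −0.00716 for H3K27me3, −0.00489 for H3K4me3 and 0.0143 for EMF2b. With 1 library left out, 113 values kept their call or stayed within the limit, 23 moved, 5 reversed and 3 lost the call. The ranges were 3533 to 3960 lost and 1052 to 1574 gained regions for H3K27me3, 1562 to 1835 lost for H3K4me3, and 2809 to 3823 lost and 3639 to 5518 gained for EMF2b. In length they were 5.64 to 6.28 Mb lost and 2.35 to 3.40 Mb gained for H3K27me3, 2.70 to 2.99 and 2.45 to 2.96 Mb for H3K4me3, and 2.71 to 3.97 and 1.78 to 3.01 Mb for EMF2b; all lie above the main values because fewer libraries then have to agree. Odds ratios ranged from 0.885 to 1.04 for H3K27me3 loss at bivalent regions, 0.922 to 1.07 for H3K27me3 loss at PLT5-bound regions, 0.414 to 1.16 for EMF2b gain rather than loss at PLT5-bound regions, and 0.964 to 1.21 for EMF2b loss with H3K27me3 loss. Peak number at equal numbers of peaks is fixed by construction and was left out. Settings that need gene positions (gene body, distance from a transcription start, gene length strata, PLT5 peak position and gene lists) were not run, nor was base overlap for H3K4me3 gains, which have no WT bases to overlap. Unknown read depth limits all counts.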

Other observations

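The tests on peak strength, on disagreement of replicates, on EMF2b sites without PLT5, on the strongest PLT5 sites and on runs of lost regions were chosen after the result was seen, as was the use of the planned equal covered length to test weaker peak calling; the tests on EMF2b sites of plt345 alone and on joint loss of both histone marks were written before their results. The limits that decide the tests on EMF2b sites without PLT5, on the strongest PLT5 sites and on equal covered length were changed after their values were known. EMF2b sites of WT that lacked a PLT5 peak also lost histone marks in plt345. Among 3716 WT EMF2b sites without PLT5, H3K27me3 was present at 33.2 ± 0.476% in WT and 25.7 ± 0.285% in plt345 libraries and H3K4me3 at 27 ± 0.266% and 22.8 ± 0.0761% (SD, n = 2 each). Of those with the mark in both WT libraries 15.8% lost H3K27me3 and 12% lost H3K4me3, against 12.3% and 7.51% at PLT5 sites (odds ratios 0.751 and 0.595, Fisher's exact test p = 0.00369 and p = 1.16e-05). The sets of sites were not matched for peak strength. EMF2b itself, where present in both WT libraries, was lost at 41.7% of the sites without PLT5 and 6.41% of PLT5 sites. The marks differed at 4466 plt345 EMF2b sites without PLT5: H3K27me3 fell from 33.7 ± 0.712% to 27.2 ± 0.111%, with losses as 78.0% (exact 95% interval 72.6 to 82.8%) of its changes, while H3K4me3 was at 35.6 ± 0.475% and 35.2 ± 0.222% (SD, n = 2 each). Over all H3K27me3 regions losses likewise outnumbered gains, at 2412 against 762, so that share is not particular to these sites. Lost H3K27me3 regions did not form blocks: the longest run of neighbouring lost regions was 4, on chromosome 1, against a median of 4 and a maximum of 7 in 200 shuffles.

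H3K4me3 regions lost in plt345 carried PLT5 peaks more often than kept regions. Weaker H3K4me3 peaks at PLT5 sites are argued against, since the odds ratio was 1.98 (95% interval 1.72 to 2.28) within 20 strata of WT peak strength, and so is random disagreement, since the highest odds ratio between replicates was 0.764 against at least 1.35 from WT to plt345. PLT5 binding at the site as the whole cause stays open: 78.0% (exact 95% interval 70.3 to 84.5%) of changed H3K4me3 calls at WT EMF2b sites without a PLT5 peak were losses, but 46.2% (39.8 to 52.8%) at such sites chosen in plt345, so the choice of sites cannot be separated from it. The choice of sites in WT may contribute, since at EMF2b sites of plt345 alone 41.4% (33.9 to 49.2%) of changes were losses. Higher background at accessible sites in the WT histone mark libraries stays open. Both marks were lost together at PLT5 sites with an odds ratio of 1.58 (1.08 to 2.30). Joint loss would also follow from a true effect on both marks or from weaker peak calling in plt345, so it cannot tell these apart. A direct effect of the missing PLT proteins on H3K4me3 stays open and untested. The excess was not seen for the stronger PLT5 peaks against all other regions, those with weaker PLT5 peaks included (odds ratio 0.958). The excess was not adjusted for WT H3K27me3 or EMF2b, whose own odds ratios of H3K4me3 loss were 3.05 and 2.08. Against WT EMF2b sites without PLT5 the direction turned, with H3K4me3 lost at 7.51% of PLT5 sites and 12% of those sites. The sets of sites were not matched for peak strength.

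The strongest PLT5 sites carried H3K27me3 and EMF2b peaks more often than the remaining sites. Of the 100 strongest sites 89% had H3K27me3 in WT and 61% in plt345, against 45.5% and 35.5% of the rest, 100% had EMF2b in WT against 76.4%, and 27 of the 100 lay on chromosome 12 against 4.88% of the rest. The odds ratio of H3K4me3 there was 0.957 (95% interval 0.633 to 1.45), at 65% against 66.0%, and that of H3K27me3 9.69 (5.17 to 18.2). This argues only against sites that attract reads equally with any antibody as the whole cause. Peak strength was shared between antibodies. Of the 100 strongest PLT5 sites, 49 were among the 100 strongest EMF2b sites of WT and 64 among those of plt345. The strongest PLT5 site also had the highest H3K27me3 −log10 q of both WT lists (52.2 and 56.5). A full need of EMF2b peak calls at these sites for PLT3, PLT4 and PLT5 is argued against, since 100% of them (exact 95% interval 96.4 to 100%) kept EMF2b in both plt345 libraries. A call can outlast a large fall in signal. The site ranked 10 for PLT5 had a WT EMF2b −log10 q of 118 and 116, against list minima of 3.56 and 3.83. If read attraction makes these peaks, their presence says nothing about EMF2b. A part played by such read attraction, for which IgG is not analysed here, a lower amount of EMF2b in plt345 that peak presence does not show, and true Polycomb targets among the strongest PLT5 sites stay open.

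More H3K27me3 regions were lost than gained in plt345. Weaker peak calling in the plt345 H3K27me3 libraries could account for the excess and stays open, since the settings part: the ratio of lost to gained regions was 0.485 at equal covered length per library, but equal numbers of peaks left 1455 lost and 1319 gained regions, and 2.91 Mb lost against 2.04 Mb gained. Fewer H3K27me3 regions in the absence of the PLT proteins remain an open biological explanation, as a true loss would also lower the covered length that the first of these settings equalises.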
